A study of Mus musculus with 6 samples.

How the data were processed

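RNA was measured in 6 libraries from livers of male C57BL/6J mice, 3 fed freely and 3 fasted for 16 h. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed with Ribo-Zero and libraries were made with the TruSeq Stranded Total RNA kit, which marks the strand. The submitters' processing notes name CASAVA 1.8, TopHat2 and hg19. That build is human, while all 22564 genes of the deposited table carry mouse Ensembl identifiers, and the steps and counting program, its annotation and its strand setting are not given in the sources used here. Of the identifiers, 21839 occur in GENCODE M21, all on the same chromosome as there. Coordinates printed here are those of GENCODE M21 on GRCm38, matched by identifier. In that annotation several named genes overlap another gene, on the same strand (Eif4ebp3, Fdps, Acaca, Acadl, Dusp1, Elovl6, Spp1) or the opposite strand (such as Retsat, Mvd, Hmgcs1, Eci2, Crat, Bnip3, Usp2, Gm129, Por, Nr1i3, Ccnd1, Slc16a6, Gyk and Cux2), and their counts are uncertain to that extent.

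The deposited table gives, for each gene and library, an FPKM and an estimated count, per the file headers, with 1 line emptied for this work. The deposited counts are not raw. In each library 90.6% to 91.1% of the values above 0 were whole multiples, within 0.02, of a single step that lay between 0.840 and 1.18. The estimated counts were divided by their library's step and rounded to whole numbers. Table lines that share a symbol (162) were summed, which left 22481 symbols. Totals over these genes were 12289648, 14771818 and 13043279 in fed libraries 1, 2 and 3 and 11158002, 11639386 and 11556725 in fasted libraries 1, 2 and 3. The 10 most abundant genes took 18.2%, 22.9% and 31.4% of the counts in fed libraries 1, 2 and 3 and 22.7%, 21.9% and 17.3% in fasted libraries 1, 2 and 3. The share of fed library 2 leaves out Alb, whose 0 there is doubtful, since an exact 0 among estimated counts can be a failed estimate. Alb was the only gene listed at 0 in a library with a median of at least 1000 counts over the libraries.

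The test was fixed before the data were examined. Since the table holds both counts and FPKM, the arm fixed for counts was used, and the arm fixed for FPKM was run as an alternative. Fasted and fed libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter at its minimum count of 10, no covariate and two-sided p-values with Benjamini-Hochberg adjustment, at a threshold of 0.05. The filter left 11633 genes. The common biological coefficient of variation was 27.9%. CPM are relative to the TMM-scaled total of each library, as the cpm function of edgeR gives them. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. With 3 against 3 libraries an exact permutation test of a single gene cannot give a p below 0.1, so no such test is printed.

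Gene lists were written from general knowledge of the liver before the data were examined, and lists may share genes. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, in a single direction and does not compare the list with other genes. Named genes follow a rule fixed at the same time: 12 genes known from fasting and feeding, whatever their result; the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean count of at least 100, groups that do not overlap and a symbol other than a Gm number, Rik clone or LOC number; and in each list up to 4 members with the lowest adjusted p or, where none passes, the 2 with the highest mean. The text may name fewer of the list members, and members that move against their list. Some genes that the rule selects are not reported here.

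The tests were checked on simulated counts drawn from the means, library sizes and dispersions of these libraries for 11633 genes in the comparison of fasted with fed livers, with 200 genes changed. edgeR recovered 1.5% of the genes changed 1.5-fold, 13.4% of those changed 2-fold and 78.8% of those changed 4-fold, with 4 false calls among 66. DESeq2 1.42.0 recovered 3%, 37.3% and 90.9%, with 34 false calls among 121, and limma 0%, 10.4% and 74.2%, with 4 among 60. A list of 25 genes raised 2-fold among 60 unchanged random lists was called by camera with either correlation and by fry, and of the random lists camera called 0 and fry 2. The simulated genes were drawn independently, with the same dispersion in both groups. The random lists therefore could not show false calls among lists whose genes vary together. In the real libraries the estimated correlation reached 0.914, for the acute phase list.

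The alternatives were DESeq2 with its size factors, no filter, robust empirical Bayes, table lines as deposited, the replicate number as a block, at least a 2-fold change, each library left out in turn, and limma on log2(FPKM + 0.5) for genes with a mean of at least 1, varied in pseudocount, filter, scaling and trend. Added after the data were seen were limma on FPKM as the other arm of the fixed design, the deposited scaled counts, a run without Alb, RLE factors, libraries thinned to the shallowest total, and the acute phase score (the mean log2 CPM of the acute phase list) as a covariate. Fold changes from FPKM are on the log2(FPKM + pseudocount) scale, which understates the change of low genes. Over-representation of KEGG pathways, as the deposited table assigns them, was tested among tested genes with a pathway by a one-sided hypergeometric test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and plotting.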

Results

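The study measured RNA in the livers of male C57BL/6J mice aged 10 weeks, a widely used inbred laboratory strain. One group ate freely and the other was fasted for 16 h before the liver was taken. Each group held 3 libraries of total RNA, sequenced after removal of ribosomal RNA. The libraries are named here by feeding state and number. The labels do not say whether each library came from its own mouse, so p-values measure the spread between these libraries. Values were read for 22564 protein-coding genes, and their deposited counts summed to between 12276679 and 13289970 in the fed libraries and between 12983415 and 13139309 in the fasted libraries. The counts used here, with the scaling step of each library divided out, summed to between 12289648 and 14771818 and between 11158002 and 11639386. These sums cover the listed genes and not the full depth of a library. At this depth 3 counts corresponded to 0.187 to 0.291 CPM, the count relative to the scaled total of the library.

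The fed libraries lay further apart than the fasted libraries, with a chi-square per degree of freedom of 149 to 424 between pairs of fed libraries and of 17.2 to 57.5 between pairs of fasted libraries. The first principal component of log2 CPM held 40.4% of the variance and parted the feeding states, with fed libraries from -50.3 to -10.8 and fasted libraries from 24.4 to 45.5. The second held 28.8% and spread the fed libraries over 54.6, 15.3 and -39.3, against -18.8 to -2.39 in the fasted libraries. The acute phase list, plasma proteins and related transcripts that the liver makes more of in inflammation, had a mean log2 CPM of 8.97, 11.35 and 12.3 in fed libraries 1, 2 and 3. Fasted libraries 1, 2 and 3 lay at 11.09, 11.2 and 10.42. Saa1, a serum amyloid transcript, was at 1904, 18334 and 28404 CPM in fed libraries 1, 2 and 3 and at 13015, 13200 and 4273 CPM in fasted libraries 1, 2 and 3. Saa1 was chosen after its values were seen, and its reads can be shared with its near copy Saa2. No library was counted as a copy of another. Alb, the albumin transcript, was listed at 0 in fed library 2, while fed libraries 1 and 3 held 714557 and 396733 counts and fasted libraries 1, 2 and 3 held 747034, 687798 and 580662. An exact 0 among estimated counts can be a failed estimate, so this value is doubtful. Alb too was chosen after its values were seen.

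**Figure D1:**
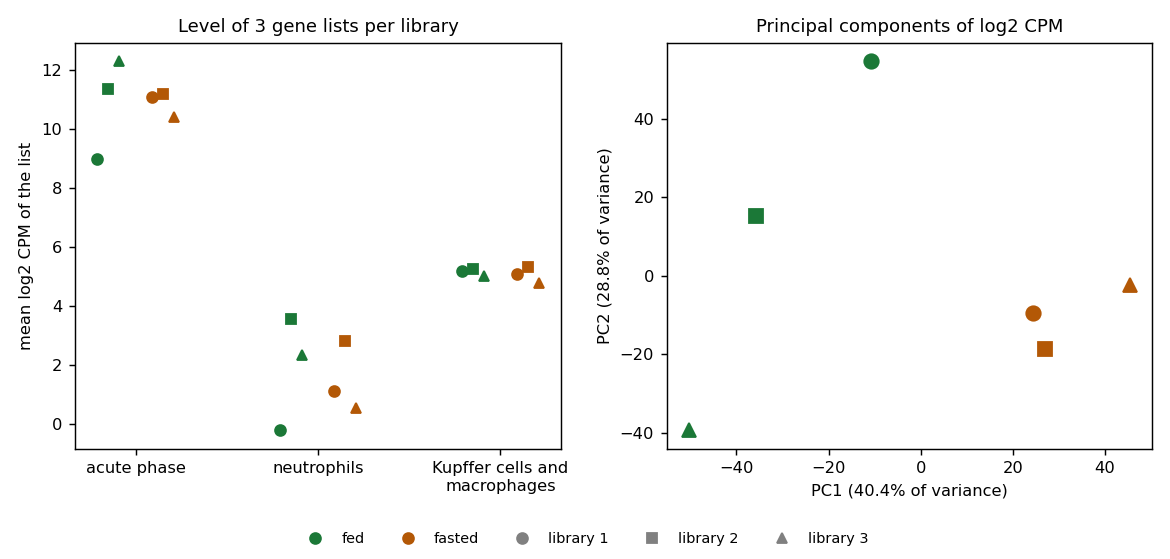
Left, mean log2 CPM of the acute phase, neutrophil and macrophage lists in each library (y axis), fed in green and fasted in brown, with the symbol giving the library number. Right, the first and second principal components of log2 CPM, with their share of the variance. The acute phase list runs from 8.97 to 12.3 among the fed libraries and from 10.42 to 11.2 among the fasted libraries.

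The comparison asked which liver transcripts differ after a 16 h fast. Transcripts of the Cyp4a family, cytochromes P450 that hydroxylate fatty acids, showed the largest rises. Cyp4a14 went from 8.17 ± 0.826 CPM in fed livers to 4292 ± 796 CPM in fasted livers (mean ± SD, n = 3 each), a 525-fold rise in edgeR's quasi-likelihood test (log2 fold change 9.04, SE 0.345, adjusted p = 0.000162). Transcripts of cholesterol synthesis fell, among them Hmgcs1, which makes HMG-CoA in the cytosol, from 526 ± 92.6 to 49.1 ± 14.8 CPM (10.7-fold lower, adjusted p = 0.00901). Cpt1a, the enzyme whose step admits long-chain fatty acids to mitochondria, rose 3.82-fold (log2 fold change 1.93, SE 0.22, adjusted p = 0.0138). Fasn, the fatty acid synthase gene, fell 7.59-fold, from 274 ± 132 to 36.2 ± 9.60 CPM (adjusted p = 0.0247). On the mouse build GRCm38 the annotation places Cyp4a14 (ENSMUSG00000028715) on chromosome 4 at 115486200 to 115496142 and Hmgcs1 (ENSMUSG00000093930) on chromosome 13 at 119690379 to 119708260. Cpt1a (ENSMUSG00000024900) lies on chromosome 19 at 3322334 to 3385733 and Fasn (ENSMUSG00000025153) on chromosome 11 at 120805846 to 120824547.

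Of 11633 genes tested, 293 changed at an adjusted p under 0.05, 164 of them higher and 129 lower in fasted livers. At least a 2-fold change was seen for 119 of the higher and 100 of the lower genes. At an unadjusted p under 0.05 there were 2535 genes. The fasted and fed values did not overlap for 29% of the tested genes, where chance gives 10% for 3 against 3, and for all 293 changed genes. On the deposited FPKM values limma called 175 genes, 78 higher and 97 lower, so that the share of higher genes was 44.6% there and 56% in the main test; on FPKM with median-of-ratios scaling it was 59.5% and with quantile normalization 56.6%. The count depended on single libraries: it was 498, 13 and 754 without fed libraries 1, 2 and 3, and 33, 3 and 30 without fasted libraries 1, 2 and 3. The 3 genes left without fasted library 2 were Cyp4a14, Cyp4a31 and Cyp4a32, and these kept their calls in each of the 27 other settings tried.

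The 8 largest rises were those of Cyp4a14, Cyp4a10, Cyp4a31, Cyp4a32, Slco1a4, Retsat, Fmo2 and Eif4ebp3. Cyp4a10 rose 187-fold, Cyp4a31 41.4-fold and Cyp4a32 22.3-fold, with edgeR adjusted p of 0.00901, 0.000162 and 0.00295. Cyp4a10 was at 19.0, 6.40 and 4.70 CPM in fed libraries 1, 2 and 3, and without fed library 1 it rose 332-fold. These genes are close copies that lie side by side on chromosome 4 between positions 115486200 and 115621602 of the mouse build GRCm38, so reads can be shared among them and each single value is uncertain. Slco1a4, a transporter of bile acids and other organic anions, rose 18.3-fold, from 7.13 ± 5.02 to 132 ± 64.0 CPM. Retsat, which saturates all-trans-retinol, rose 13.3-fold, from 57.0 ± 45.0 to 761 ± 202 CPM, and 24.1-fold without fed library 1. Fmo2, a flavin-containing monooxygenase, rose 8.83-fold, and Eif4ebp3, a binding protein of the translation factor eIF4E, rose 8.66-fold. Eif4ebp3 overlaps an annotated gene on the same strand, which leaves its count uncertain. Slco1a4, Retsat and Eif4ebp3 did not pass without fed library 2 or any fasted library, and Cyp4a10 and Fmo2 did not pass without fed library 2 or fasted library 2. With the replicate number as a block Slco1a4 and Retsat did not pass (adjusted p = 0.134 and 0.0683).

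The largest falls included those of Serpina12, Fabp5, Sqle, Fdps, Idi1, Mvd and Hmgcs1. Serpina12, which encodes the serpin vaspin, fell 31.8-fold (log2 fold change -4.99, SE 0.94, edgeR adjusted p = 0.0445). Its fed libraries 1, 2 and 3 held 84.0, 12.9 and 11.9 CPM and the fasted libraries 0.779 to 1.37 CPM. The fold rests largely on fed library 1, without which Serpina12 fell 11-fold, and the call changed in 16 of 27 other settings, FPKM with limma among them (adjusted p = 0.0802). The gene (ENSMUSG00000041567) lies on chromosome 12 at 104028769 to 104044443. Fabp5, a fatty acid binding protein, fell 17.7-fold, from 160 ± 31.4 to 9.04 ± 6.65 CPM, and 27.3-fold without fasted library 1. Sqle, Fdps, Idi1 and Mvd, all enzymes of the cholesterol pathway, fell 14.7-fold, 14.7-fold, 12.9-fold and 12.4-fold. Fdps overlaps an annotated gene on its own strand and Mvd, Idi1 and Hmgcs1 overlap genes on the opposite strand, and the strand setting of the counting is not given in the sources used here, so these counts are uncertain to that extent. Serpina12, Fabp5, Sqle, Fdps, Idi1 and Mvd did not pass without fed library 2, fasted library 1 or fasted library 2, and without fasted library 3 Serpina12, Idi1 and Mvd did not. With the replicate number as a block Serpina12, Fabp5, Sqle and Idi1 did not pass (adjusted p = 0.0683, 0.0715, 0.135 and 0.147).

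**Figure D2:**
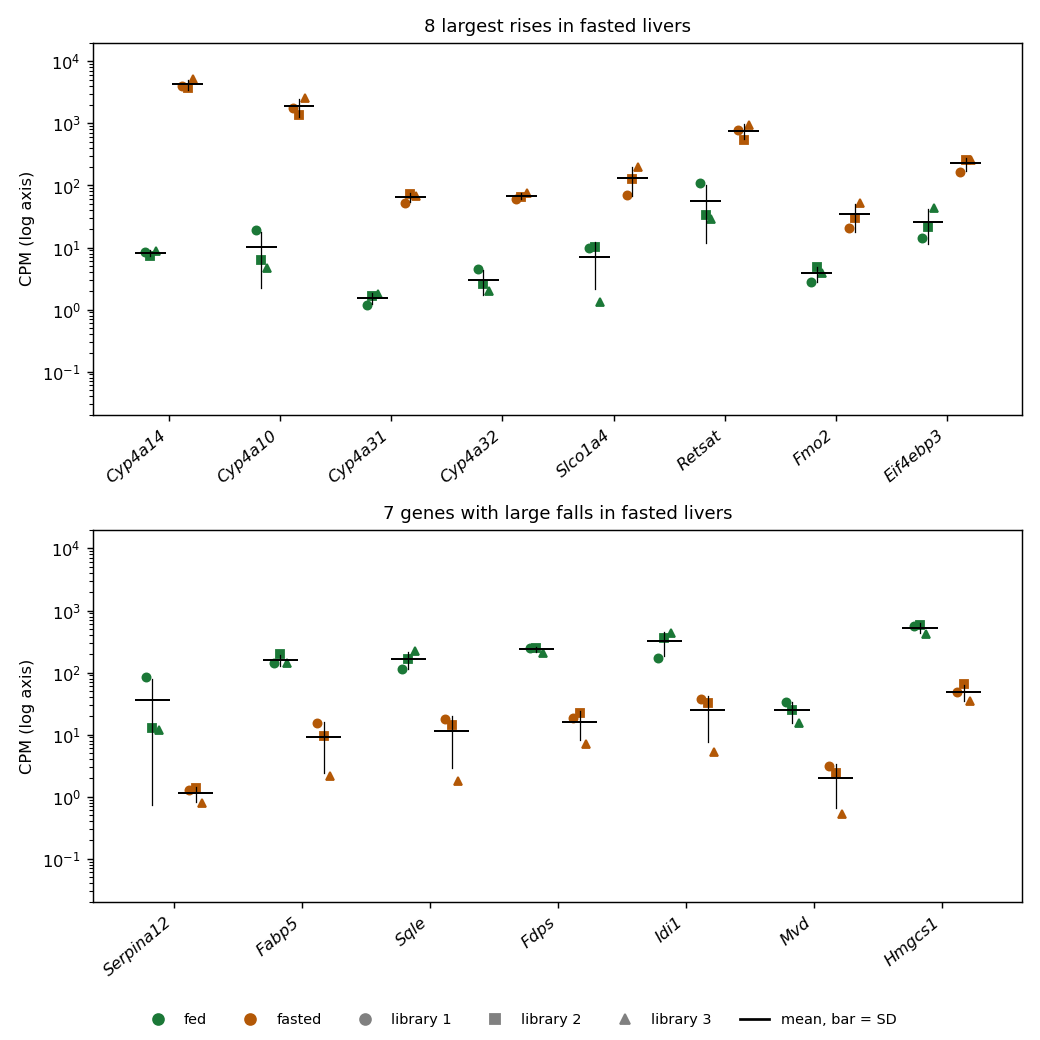
CPM on a log axis for the 8 genes with the largest rise (top) and 7 genes with large falls (bottom) in fasted livers, 3 fed libraries in green and 3 fasted libraries in brown, the symbol giving the library number. Horizontal lines are means and vertical bars are SD, shortened where they would reach below 0. Fed and fasted values do not overlap for any of these genes, and Cyp4a14 has means of 8.17 and 4292 CPM.

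Among genes fixed beforehand for their known part in fasting and feeding, Pck1, Cpt1a and Cyp4a14 rose and Fasn fell. Pck1, the cytosolic enzyme that starts gluconeogenesis from oxaloacetate, rose 2.51-fold, from 1514 ± 230 to 3806 ± 276 CPM (edgeR adjusted p = 0.0404). The gene (ENSMUSG00000027513) lies on chromosome 2 at 173153048 to 173159273. Srebf1, Fgf21, G6pc, Pdk4, Scd1 and Igfbp1 did not pass in the main test. Srebf1, a regulator of lipid synthesis, had means of 150 ± 109 and 17.8 ± 6.28 CPM in fed and fasted livers (adjusted p = 0.0583). Fgf21, a hormone secreted by the liver, was at 0, 0.0622 and 0.588 CPM in fed libraries 1, 2 and 3 and at 2.43, 2.38 and 2.68 CPM in fasted libraries 1, 2 and 3 (adjusted p = 0.0789). G6pc, Pdk4 and Scd1 had groups that did not overlap but adjusted p of 0.196, 0.145 and 0.143, and Igfbp1 had an adjusted p of 0.334 with overlapping groups. Without fed library 2 or any of the fasted libraries Pck1, Cpt1a and Fasn no longer passed, with adjusted p of 0.144, 0.0891 and 0.106 without fed library 2. On FPKM with limma Pck1 and Fasn did not pass (adjusted p = 0.0555 and 0.06), nor did Pck1 and Cpt1a with the replicate number as a block in edgeR (0.163 and 0.0702). The calls of Pck1, Fasn and Cpt1a changed in 12, 12 and 6 of 27 other settings. Fgf21 passed with DESeq2 (adjusted p = 0.00231), FPKM with limma (0.0334), edgeR without fed library 3 (0.0115) and edgeR after thinning (0.0432). The result of Fgf21 changed in 11 of 26 other settings and that of Srebf1 in 4 of 27.

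**Figure D3:**
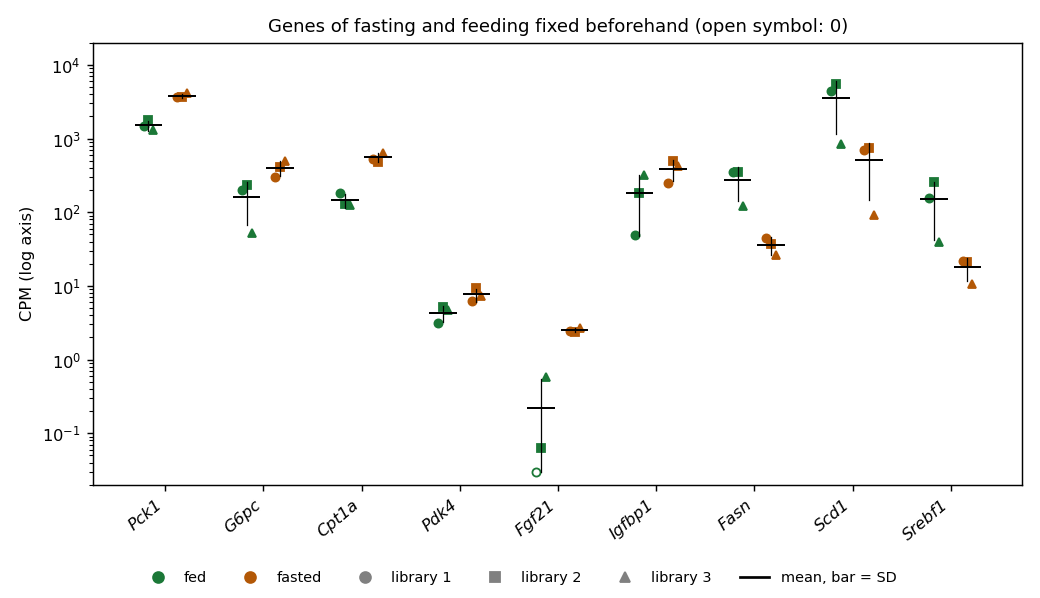
CPM on a log axis for 9 of the genes fixed beforehand (Cyp4a14 is drawn with the largest rises), fed libraries in green and fasted libraries in brown, the symbol giving the library number and an open symbol a value of 0. Lines are means and bars are SD. Scd1 in fed library 3 (834 CPM) lies near fasted libraries 1 and 2 (694 and 736 CPM), and Pck1 has means of 1514 and 3806 CPM.

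Gene lists written before the data were examined were tested as groups. Of 39 lists, 36 had at least 3 tested members, and camera with a preset correlation of 0.01 called 22 of them, 16 higher and 6 lower in fasted livers. Other splits of the 6 libraries into 3 and 3 called 7 to 25 lists in the same way. Of the 10 splits 3 called at least 22, the real one included. The number of called lists therefore does not by itself part the feeding states. None of the 22 passed with a correlation estimated from these libraries, where adjusted p ran from 0.171 to 0.66, and fry called 12, all of them among the 22. Fry called the lists of cholesterol synthesis, PPARA targets, mitochondrial and peroxisomal fatty acid oxidation, lipid droplets and amino acid catabolism. It also called the urea cycle, gluconeogenesis, autophagy, clock, female-biased and periportal lists. The other called lists did not pass with fry, among them de novo lipogenesis (fry adjusted p = 0.19) and the unfolded protein response (0.141). The estimated value for each list is given beside its call.

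Cholesterol synthesis fell as a group. Of its 26 tested members 19 fell and none rose, and 25 fell when adjusted over the list alone. The median log2 fold change was -2.30 (camera adjusted p = 5.34e-23; adjusted p = 0.228 with an estimated correlation). Dhcr7, the reductase of the last step, fell 5.53-fold and Nsdhl 9.32-fold. As single genes 19, 5 and 22 of them passed without fed libraries 1, 2 and 3, and 7, 0 and 12 without fasted libraries 1, 2 and 3.

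De novo lipogenesis fell too: 5 of 22 tested members fell, none rose, and the list alone gave 14 falls and 2 rises. The median log2 fold change was -1.11 (camera adjusted p = 9.45e-06; adjusted p = 0.463 with an estimated correlation). Elovl6, which lengthens C16 fatty acids, fell 6.81-fold, Rdh11 3.80-fold and Acaca, the acetyl-CoA carboxylase of the cytosol, 2.37-fold. Lpin1, a phosphatidate phosphatase, had a log2 fold change of 2.01, against the rest of the list, and did not pass (edgeR adjusted p = 0.0664). Within the fed group the list lay lower in library 3 than in library 1 by a median log2 difference of -1.47, while the acute phase list lay higher there by 2.85. None of the members passed without fed library 2 or without any of the fasted libraries, and 18 passed without fed library 3.

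PPARA targets, genes driven by the fatty acid receptor PPAR alpha, rose as a group. Of 26 tested members 10 rose and none fell, and 20 rose when adjusted over the list alone, with a median log2 fold change of 1.70 (camera adjusted p = 2.98e-18; adjusted p = 0.171 with an estimated correlation). The list shares its strongest members, the Cyp4a genes, with the largest rises. Mitochondrial fatty acid oxidation rose in 5 of 20 members (14 when adjusted over the list alone; camera adjusted p = 5.06e-12; adjusted p = 0.288 with an estimated correlation). Acadm and Acadl, acyl-CoA dehydrogenases of the beta-oxidation spiral, rose 2.69-fold and 2.38-fold, and Slc25a20, the carnitine-acylcarnitine carrier, 2.15-fold. Peroxisomal fatty acid oxidation rose in 3 of 17 members (10 when adjusted over the list alone; camera adjusted p = 3.18e-10; adjusted p = 0.228 with an estimated correlation), namely Crat, Eci2 and Ech1, by 2.29-fold, 2.33-fold and 3.09-fold. All tested members of both oxidation lists had an estimate above 0. Of the PPARA targets 15, 3 and 16 passed without fed libraries 1, 2 and 3, and 5, 3 and 4 without fasted libraries 1, 2 and 3. No member of either oxidation list passed without fed library 2 or any of the fasted libraries, while 12 mitochondrial and 7 peroxisomal members passed without fed library 1 and 5 and 7 without fed library 3.

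Lipid droplet and lipoprotein genes rose in 4 of 24 members (10 rises and 1 fall when adjusted over the list alone; camera adjusted p = 6.99e-06; adjusted p = 0.266 with an estimated correlation). Pnpla2, the adipose triglyceride lipase, rose 3.55-fold from 30.3 ± 3.42 to 108 ± 5.89 CPM, the droplet protein Plin5 3.03-fold and Apoa5 2.30-fold. Ketogenesis was not called (camera adjusted p = 0.406), and its median of -0.04 and mean of 0.06 differed in sign. Of its 7 tested members 1 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone. Slc16a6, a monocarboxylate transporter, fell 2.73-fold from 20.1 ± 4.95 to 7.33 ± 1.43 CPM (edgeR adjusted p = 0.0307). Of the lipid droplet list 5, 1 and 8 members passed without fed libraries 1, 2 and 3 and 2, 0 and 1 without fasted libraries 1, 2 and 3, and Slc16a6 did not pass without fed library 2 or any fasted library.

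Genes of amino acid breakdown and of glucose synthesis were higher in fasted livers. Amino acid catabolism rose in 6 of 36 members (16 when adjusted over the list alone), with a median log2 fold change of 0.93 (camera adjusted p = 1.2e-12; adjusted p = 0.266 with an estimated correlation). Got1, the cytosolic aspartate aminotransferase, rose 6.99-fold from 86.3 ± 10.8 to 603 ± 231 CPM, Tdo2, which opens the tryptophan ring, 3.90-fold, Gpt2 3.08-fold and Cdo1, the cysteine dioxygenase, 3.16-fold. In the urea cycle list 1 of 8 members passed (6 when adjusted over the list alone; camera adjusted p = 0.000113; adjusted p = 0.266 with an estimated correlation). It was Asl, the argininosuccinate lyase, which rose 6.38-fold from 190 ± 54.4 to 1215 ± 225 CPM. Gluconeogenesis rose in 3 of 12 members (10 when adjusted over the list alone; camera adjusted p = 1.03e-07; adjusted p = 0.171 with an estimated correlation): Pck1, the glucose 6-phosphate carrier Slc37a4 (2.42-fold) and the glycerol kinase Gyk (2.08-fold). The calls of Asl and of the gluconeogenesis genes were lost without fed library 2 or any fasted library, and 2 gluconeogenesis genes passed without fed library 1. Of the amino acid list 11, 0 and 12 members passed without fed libraries 1, 2 and 3 and 1, 0 and 1 without fasted libraries 1, 2 and 3, and of the urea cycle list 3 without fed library 1 or 3.

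Bile acid genes went both ways. Of 25 tested, Slco1a4 and Abcc3, an exporter in the basolateral membrane, rose (Abcc3 3.45-fold), and Cyp2c70, which makes muricholic acid in mice, fell 9.17-fold from 1563 ± 210 to 170 ± 63.7 CPM. The list was called as higher (camera adjusted p = 0.00539; adjusted p = 0.66 with an estimated correlation), with 4 rises and 1 fall when adjusted over the list alone. Xenobiotic metabolism rose in 4 of 30 members (7 when adjusted over the list alone; camera adjusted p = 2.68e-06; adjusted p = 0.421 with an estimated correlation). Cyp2e1, an ethanol-oxidising cytochrome P450, rose 4.33-fold to 10619 ± 2335 CPM, Por, the electron donor of these enzymes, 4.57-fold, and the receptor gene Nr1i3 3.33-fold. Within the fed group the xenobiotic list lay lower in library 3 than in library 1 by a median log2 difference of -1.75. Of the xenobiotic list 6, 0 and 9 members passed without fed libraries 1, 2 and 3 and none without any fasted library, and of the bile acid list 6, 0 and 7 and then 0, 0 and 1.

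The unfolded protein response list, chaperones and folding enzymes of the endoplasmic reticulum, was lower in fasted livers. Of 25 members 2 fell and none rose, and the list alone gave 20 falls and 1 rise, with a median log2 fold change of -1.03 (camera adjusted p = 1.9e-09; adjusted p = 0.421 with an estimated correlation). Pdia6, a protein disulfide isomerase, fell 3.60-fold from 529 ± 103 to 147 ± 74.3 CPM and Fkbp11 4.6-fold. All 25 members lay higher in fed library 3 than in fed library 1, by a median of 0.70 on the log2 scale. In this list 8, 0 and 4 members passed without fed libraries 1, 2 and 3, and 4, 0 and 0 without fasted libraries 1, 2 and 3. Proliferation genes were called lower with 1 of 23 members passing over all genes and over the list alone (camera adjusted p = 0.00272; adjusted p = 0.66 with an estimated correlation), namely Ccnd1, the cyclin of the G1 phase, which fell 8.67-fold; camera's adjusted p was 0.255 without fed library 2 and 0.118 without fasted library 3, and the call of Ccnd1 was lost without fed library 2 or any fasted library.

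Autophagy and lysosome genes rose in 2 of 28 members (4 when adjusted over the list alone; camera adjusted p = 1.47e-05; adjusted p = 0.171 with an estimated correlation), the mitophagy receptor Bnip3 by 3.44-fold and Map1lc3a by 1.94-fold. Glucocorticoid targets rose in 2 of 18 members (3 when adjusted over the list alone; camera adjusted p = 0.000801; adjusted p = 0.421 with an estimated correlation), Dusp1 by 2.40-fold and Klf9 by 2.01-fold. The clock list rose in 2 of 21 members, over all genes and over the list alone (camera adjusted p = 0.0339; adjusted p = 0.266 with an estimated correlation): Usp2 by 5.01-fold and Gm129, the gene now named Ciart, by 9.29-fold. The clock call was lost without fasted library 3, at an adjusted p of 0.0575. The list had a mean log2 CPM of 3.87, 3.71 and 3.22 in fed libraries 1, 2 and 3 and of 4.21, 4.06 and 4.28 in fasted libraries 1, 2 and 3, and the clock output genes Dbp, Tef, Hlf, Per3, Nr1d1 and Nr1d2, grouped after the data were seen, differed by a median of -2.72 (log2) between fed library 3 and fed library 1. The list of the citrate cycle and oxidative phosphorylation was called higher with a median log2 fold change of 0.25 and no member passing, over all genes or over the list alone (camera adjusted p = 0.00127; adjusted p = 0.66 with an estimated correlation); camera's adjusted p was 0.0997 without fed library 3. Atp5b in that list had means of 693 ± 232 and 876 ± 91.6 CPM. The single-gene calls of the autophagy, glucocorticoid and clock lists were lost without fed library 2 and without each fasted library.

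Lists of genes known to differ between male and female livers were tested too. The female-biased list rose in 3 of 11 members (6 rises and 1 fall when adjusted over the list alone; camera adjusted p = 0.000347; adjusted p = 0.266 with an estimated correlation), among them Fmo2 and the transcription factor gene Cux2. Cux2 was at 0.212, 0.497 and 0.0840 CPM in fed libraries 1, 2 and 3 and at 3.5, 4.57 and 1.64 CPM in fasted libraries 1, 2 and 3, so low in fed livers that no fold is given. The male-biased list had 21 of 23 estimates below 0 with a median of -1.14 (1 fall over all genes and 2 over the list alone; camera adjusted p = 0.0106; adjusted p = 0.66 with an estimated correlation). Its called member was Capn8, which fell 3.04-fold. Between fed library 3 and fed library 1 the female-biased list differed by a median log2 difference of 1.38 (SE 0.63 over its genes), against its median of 1.12 between fasted and fed livers. The male-biased list differed there by -2.09, and without fed library 1 its call was lost (camera adjusted p = 0.819). The female-biased call was lost on FPKM with median-of-ratios scaling (0.115) and quantile normalization (0.113). Of its members 2, 0 and 6 passed without fed libraries 1, 2 and 3 and 1, 0 and 1 without fasted libraries 1, 2 and 3, and of the male-biased list 2, 0 and 6 and then none.

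Markers of the zones and other cells of the liver were tested in the same way. The periportal list was called higher (1 of 15 members, 6 when adjusted over the list alone; camera adjusted p = 8.6e-05; adjusted p = 0.266 with an estimated correlation), its called member being Hsd17b13, which rose 2.59-fold. The call of Hsd17b13 was lost without fed library 2 or any fasted library. Hsd17b13 also stands in the lipid droplet list, and Hal, Sds, Gls2, Uroc1, Ass1, Arg1 and Cps1 in the amino acid or urea cycle lists. The periportal call is therefore not separate from the calls of those lists. The pericentral list was not called (camera adjusted p = 0.728), with Cyp2e1 passing of 19 and 3 rises and 1 fall over the list alone. Its median of -0.11 and mean of 0.11 differed in sign. Cholangiocyte markers were called lower with none of 6 members passing (2 when adjusted over the list alone; camera adjusted p = 0.0357; adjusted p = 0.266 with an estimated correlation). Spp1 led this list with 32.1, 122 and 502 CPM in fed libraries 1, 2 and 3 against 11.9 to 26.4 CPM in the fasted libraries, and the call was lost without fed library 2, at an adjusted p of 0.0865, and without fasted libraries 1 and 3, at 0.0506 and 0.122, as well as on FPKM with limma, at 0.105. Erythroid markers were called higher with none of 7 passing, over all genes or the list alone (camera adjusted p = 0.0339; adjusted p = 0.62 with an estimated correlation). Hbb-bs had means of 43.5 ± 24.2 and 100 ± 31.9 CPM, and the call was lost without fed libraries 2 and 3 and fasted libraries 1 and 2, at adjusted p of 0.0719, 0.0875, 0.0523 and 0.0515, and on FPKM with a mean of at least 5, median-of-ratios scaling or quantile normalization, at 0.0851, 0.0618 and 0.0649.

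**Figure D4:**
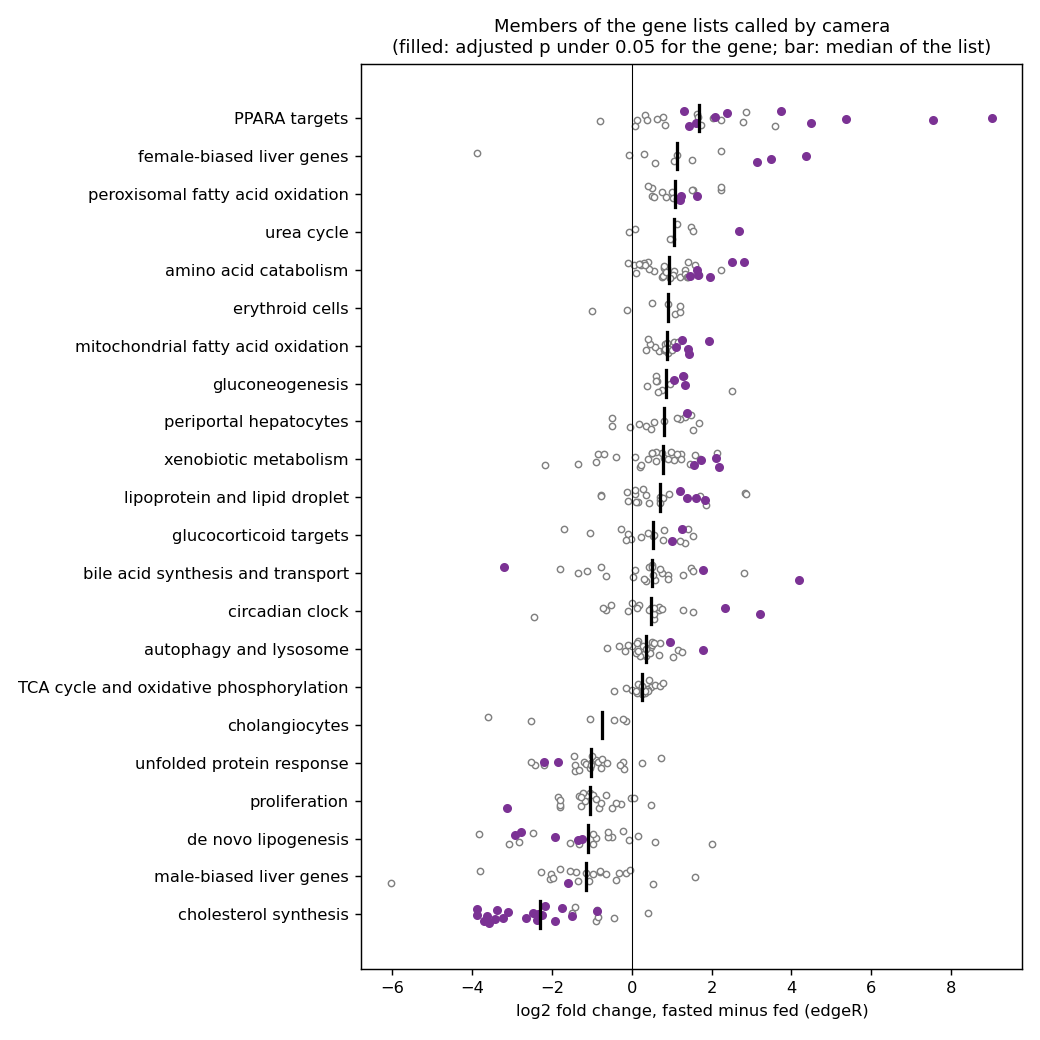
Log2 fold change (fasted minus fed, x axis) of each tested member of the 22 gene lists called by camera with a preset correlation, ordered by the list's median (bar). Filled points are genes with an adjusted p under 0.05 in edgeR and open points are the others. The median runs from -2.30 for cholesterol synthesis to 1.70 for PPARA targets.

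Of the 36 tested lists 14 were not called, with camera adjusted p from 0.0936 to 0.952. Besides the ketogenesis and pericentral lists they held the acute phase response (0.952), where Hpx, the hemopexin transcript, had means of 27699 ± 20900 and 20761 ± 5628 CPM, and glycogen metabolism (0.768), where Pygl, the liver glycogen phosphorylase, had means of 271 ± 184 and 159 ± 8.75 CPM. Of glycolysis and fructose use (0.223) 1 of 20 members fell, with 3 rises and 1 fall when adjusted over the list alone. Insulin and FOXO signalling (0.214) and ribosome biogenesis (0.852) had no member that passed either way, and the ATF4 and amino acid response (0.218) had 2 rises and 2 falls over the list alone. Of the immediate early and heat shock genes (0.852) the small heat shock gene Hspb1 fell 3.04-fold, over all genes and over the list alone. Camera's direction differed in sign from the median for the acute phase, ketogenesis, glycogen, ribosome biogenesis, pericentral and endothelial lists.

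Among markers of other cells, macrophages (camera adjusted p = 0.47), endothelial cells (0.81) and neutrophils (0.489) had no member passing, over all genes or over the list alone, and T and NK cells (0.572) had 1 fall over the list alone. Cd5l, a macrophage transcript, had means of 196 ± 46.7 and 215 ± 56.9 CPM, and S100a8, a neutrophil transcript, was at 2.19, 54.7 and 38.3 CPM in fed libraries 1, 2 and 3 and at 12.1, 33.0 and 7.36 CPM in fasted libraries 1, 2 and 3. Of stellate cell and fibroblast markers (0.0936) Ngfr, a neurotrophin receptor, fell 2.99-fold from 4.12 ± 0.585 to 1.37 ± 0.159 CPM (2 falls over the list alone). Too few members were tested for 3 lists: B cells with Cd74 and Cd22 (edgeR adjusted p = 0.760 and 0.951), the adipocyte list with Car3 (0.225) and the acinar cell list with Cela1 (0.149). Car3, a carbonic anhydrase, was at 1719, 63.3 and 4.53 CPM in fed libraries 1, 2 and 3 and at 33.8, 11.6 and 48.5 CPM in fasted libraries 1, 2 and 3. Ngfr passed without fed library 3 and lost its call without each of the other libraries, and so did Hspb1, the heat shock gene above.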

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

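The settings added after the data were seen were FPKM with limma, the deposited scaled counts, the run without Alb, RLE factors, thinning and the acute phase covariate; all others were planned. The main test called 293 genes, 164 higher and 129 lower, and 22 lists. In 10 settings the count lay between 198 and 324. DESeq2 called 1054 (557 higher, 497 lower), all 293 among them, and in the simulation it made more false calls than edgeR. The simulation gave both groups the same dispersion, while the real fed libraries lay further apart than the fasted ones. The simulated rates of either tool need not hold for these libraries. Leaving out 1 library gave 3 to 754 genes, 3 to 366 higher and 0 to 388 lower, and without fasted library 2 edgeR called 0 lower genes, with 1817 genes at an unadjusted p under 0.05. FPKM with limma called 175 (78 higher), 160 (71) with a pseudocount of 0.1, 180 (81) with 1, 174 (85) for a mean of at least 5, 168 (78) without a trend and 188 (84) with robust variances. With median-of-ratios scaling it called 227 (135 higher, 92 lower) and with quantile normalization 198 (112 higher, 86 lower), where higher genes outnumbered lower ones as in the main test. Without a filter it called 35 (15 higher, 20 lower) and with libraries scaled to the same total 108 (49 higher, 59 lower). The acute phase covariate gave 1310 (777 higher, 533 lower), all 293 among them; the same scores rearranged within the groups gave 72 to 1502, with 5 of 36 arrangements giving as many, the real one included, and 60 random lists of matched genes gave 0 to 1253. Camera with an estimated correlation called 0 lists and fry 12. With the replicate number as a block 29 genes passed (15 higher, 14 lower), 28 of them among the 293. Equal numbers gave no sign of a pairing. The correlations of their deviations were -0.074, 0.183 and -0.126, and 2 of 6 libraries correlated best with their own number. With 3 libraries per group these values cannot exclude a pairing.

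Of 100 named genes 65 were called, and 3 kept the call in all 27 settings; 15 of the 22 called lists kept theirs in all 25 settings that used camera with the preset correlation, and with an estimated correlation none did. Genes gave 26 reversals in 2640 values and lists 0 in 549, and none of the reversed genes passed. With 1 library left out Egfr ran from -0.037 (without fed library 1) to 0.25, and it was -0.088 with quantile normalization. Igf1 was -0.050 on FPKM as deposited, with each pseudocount or filter, without a trend and with robust variances, -0.031 with libraries scaled to the same total and -0.22 with quantile normalization. Hpx ran from -0.90 to 0.28 (without fed library 3) and was 0.14 with quantile normalization, and Fga ran from -0.75 to 0.29 (without fed library 3). Cd5l ran from -0.072 (without fasted library 2) to 0.29, was also below 0 without fed library 3, and was -0.017 with quantile normalization. Il2rb ran from -0.14 to 0.64, below 0 without fed library 2, fed library 3 or fasted library 2. Cd74 ran from -0.80 to 0.41 (without fed library 1) and was 0.015 with the covariate. Cd22 ran from -0.14 to 0.35, below 0 without fed library 1, fed library 3 or fasted library 2, and was -0.0032 on FPKM without a filter. The cause was not tested.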

Other observations

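The splits of changed genes were planned, the thinning and the macrophage test were chosen after the data were examined but before their own results were seen, and the tests of pathways, of the other splits, of neutrophils, abundant genes, the negative acute phase list and the clock were chosen after the pattern was seen. The genes named in the next sentences were likewise chosen after their values were seen. Mat1a, which makes S-adenosylmethionine in the liver, rose from 2169 ± 854 to 12358 ± 1189 CPM (n = 3 each, edgeR adjusted p = 0.0291), and Ahcy, which splits S-adenosylhomocysteine, rose 3.67-fold (adjusted p = 0.0171). The cysteine and methionine pathway held 5 of the genes that rose among its 41 tested members (hypergeometric adjusted p = 0.0269), but 1 of these, Gm4737, resembles Ahcy and can share its reads. Retinol metabolism held 9 of 62 (adjusted p = 7.15e-05), among them Retsat, Rdh9, a retinol dehydrogenase gene that rose 4.65-fold, and the Cyp4a genes, whose reads can be shared; 3 others of the 62 fell (Aldh1a7, Cyp2c70 and Rdh11). In amino sugar and nucleotide sugar metabolism 5 of 43 fell (adjusted p = 0.042), among them Nans, the sialic acid synthase, by 5.35-fold, Cmah, which hydroxylates sialic acid, by 3.07-fold and Uxs1 by 1.83-fold. Of the 275 pathways tested in each direction 8 passed for genes that rose and 4 for genes that fell. The others were PPAR signaling (2.07e-05), fatty acid degradation (5.52e-05), arachidonic acid (5.52e-05), linoleic acid (0.00223), TRP channel regulation (0.00325) and chemical carcinogenesis (0.0269) for rises, and terpenoid backbone (1.67e-07), steroid synthesis (1.89e-07) and fatty acid metabolism (0.00413) for falls. Of the 41 genes of fatty acid metabolism 6 fell, while 3 rose (Acadl, Acadm and Cpt1a). PPAR signaling and fatty acid degradation each held 2 genes that fell. Most of the pathways of the rises shared the Cyp4a or Cyp2c genes. With Gm4737 and Ahcy counted once, and the Cyp4a genes once, the cysteine and methionine pathway and TRP channel regulation no longer passed (adjusted p = 0.131 and 0.229), and retinol metabolism held 6 of 59 (0.0272). Cyp2c38 and Cyp2c39, members of the same gene family in the retinol pathway, were still counted separately. The pathway test took genes as independent and used the calls of the main test and of no other setting. Without fasted library 2 edgeR called 0 lower genes, so no pathway of falls could pass there. Mat1a, Ahcy, Nans, Cmah and Uxs1 did not pass without fed library 2 or any fasted library, nor Uxs1 without fed library 1 (edgeR adjusted p = 0.0625). Rdh9 did not pass without fed library 2 or fasted libraries 2 and 3 (0.0713, 0.078 and 0.0504).

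The real split of the 6 libraries called 293 genes, 164 higher and 129 lower, and the highest of the other splits called 1 gene in total and the rest none. A split and its mirror count once, so that 1 gene was set against both the rises and the falls. Only 1 of the 10 splits gave a count as large as the real one, in total, for rises and for falls. For lists 3 of the 10 splits gave as many, with 22 in the real split and 25 in the highest other. The splits are too few for a share under 0.05. The fed libraries were deeper by the counts used here, though not by the deposited counts, and after thinning to the shallowest total 272 of the 293 genes passed again, which argues against depth as the main source of the calls.

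Acute phase transcripts lay apart among the fed livers, by a median log2 difference of 2.85 between fed libraries 3 and 1. More macrophage RNA in fed library 3 would raise macrophage markers there too. These differed by -0.33, which argues against a larger share of macrophage RNA in that library. An effect of macrophages on other cells would need no such difference and was not tested. A different share taken by a few abundant genes would scale all other genes of a library alike. The list lay above the median of all other tested genes by 2.86 (SE 0.46), with all 24 members higher in fed library 3. The scaling centres the other genes near 0 (median 0, SE 0.01), so this value restates the spread of 2.85. The comparison could hardly have come out otherwise, and that explanation stays open. Neutrophils differed with the same sign as the acute phase list in 2 of 3 pairs of fed libraries and stay open there. Between fed libraries 3 and 1 they differed by 2.71 (SE 0.94). Between fed libraries 3 and 2 they differed by -0.82 (SE 0.39), against 0.65 (SE 0.08) for the acute phase list. That argues against them for this pair, though these standard errors treat the genes of a list as independent. An acute phase response of individual livers stays open as well: a list of 24 transcripts known to be lower in that state, 18 of which also stand in the fixed lists, differed by -2.14 (SE 0.39), as it would then, but this was found and tested in the same libraries.

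Clock output genes (Dbp, Tef, Hlf, Per3, Nr1d1 and Nr1d2) also lay apart among the fed livers, with all 6 lower in fed library 3 than in fed library 1 and a median log2 difference of -2.72. Dbp was at 21.1, 5.47 and 0.756 CPM in fed libraries 1, 2 and 3 and at 17.5, 3.47 and 17.5 CPM in fasted libraries 1, 2 and 3. Livers taken at different times of day could give this, and then Arntl, Npas2, Clock and Cry1 would differ the other way. Their median difference was 0.99 (SE 0.54), less than 2 standard errors from 0. That standard error runs over these genes, taken as independent, between only 2 libraries. The hour of sampling is not given in the sources used here, so this explanation stays open. No biological explanation of the clock difference was tested.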
